A study of Mus musculus with 4 samples.

How the data were processed

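Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for the chromatin-associated ubiquitin ligase Trim33 in mouse T helper 17 (Th17) cells made in culture. The labels give 2 Trim33 ChIP libraries and 2 input DNA libraries, 4 in all. The deposited peak list was made from the merged replicates, so it holds 1 value per peak and no value per library. The spread between cultures, the depth of each library and the control used for calling are therefore unknown here. Per the submitters' processing notes, the tools were Trim Galore 0.3.7, Bowtie 1.2.1.1 and MACS2 2.1.1.20160309, with the build mm10. The settings and the calling threshold are not given in the sources used here.

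Each peak in the deposited list has a start, an end, a summit and 4 values that are the authors'. The deposited fold enrichment is a ratio that the authors' peak caller, MACS2 per the submitters' processing notes, made by dividing the signal at the summit by its background. The deposited list also gives the −log10 of the p-value and the −log10 of the q-value at the summit. The authors' score equalled the whole part of 10 times the −log10 q in 100% of the peaks and was not used further. These values were used to describe, rank and filter peaks within this list. Merging replicates before calling favours sites with reads in the sum of both libraries, whether or not each library alone would give a peak. Coordinates are given counted from 1.

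Genes were taken from a RefSeq table of the same assembly, with 21887 protein-coding genes on the chromosomes used. This table gives the start and end of each gene, but strand, exons and sequence were not used here. A promoter could thus not be told from the 3′ end of a gene. In place of the planned promoter window, a summit within 1000 bp of either end of a protein-coding gene was called a gene-end summit, and this wider definition applies to every promoter result that was planned. The planned genic classes were reduced in the same way to gene end, gene body, within 10 kb of a gene and farther away. A locus was the gene body with 10 kb on each side. Summits of a locus that lay over 1000 bp from the ends of all protein-coding genes were called distal.

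The share of regions in each class was compared with 1000 random placements of the regions, with chromosome and width kept, between the first and last annotated gene of each chromosome. Sequence gaps were not excluded. Alternatives used 200 placements, except placement anywhere on the chromosomes and regions moved by 20 to 100 kb, which used 1000. The 17 gene lists were compared with 10000 random lists of protein-coding genes of the same size. For loci the random lists were also matched on 10 bins of locus length. The p-values are two-sided, and those of lists are adjusted by Benjamini-Hochberg over the 17 lists, with a threshold of 0.05. Genes are not independent replicates, and peaks are not either, so these p-values describe this peak list and not the spread between cultures. Fold values of gene-end and other peaks were compared by a permutation test of the difference of medians with 100000 resamples. Counts of 2 lists were compared by Fisher's exact test. Intervals of shares are exact binomial (Clopper-Pearson) intervals and cover counting error only. The interval of a list fold over another background is that of the share divided by the expected share. It takes genes as independent draws and leaves out the spread of random lists.

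The gene lists, the rule for named genes, the tests against random placement and random lists and the test of peak values were fixed before the data were examined. Tests between lists, of gene families and classes and of the highest peaks were added later, as were regions moved by 20 to 100 kb, sets ranked by −log10 q and other backgrounds of random genes. The rule takes 16 genes of the Th17, IL-10 and TGF-beta setting whether or not they hold a peak, and up to 3 members of each list with the highest fold in the locus. It also takes the genes with an end nearest to the 10 highest peaks and at most 2 members of each list with no peak. Some genes that the rule names are not reported here. The share at gene ends and the length-matched list test by locus were checked on simulated placements with known answers. With 0%, 10% and 20% of regions planted at gene ends, the true shares at gene ends were 3.14%, 12.8% and 22.5%, and 3.23%, 13.0% and 22.4% were recovered. Of 400 simulated lists of 24 random genes, 1.75% to 3.75% were called. Of 200 lists with 12 planted members, 93%, 75% and 63% were called at these 3 levels. These simulated calls used p below 0.05 without adjustment, so their rates do not apply to the adjusted calls below. The list test at gene ends was not simulated.

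The alternatives were stricter peak sets, other windows and loci, placement anywhere on the chromosomes, regions moved by 20 to 100 kb and other backgrounds of random genes. A background without Olfr, Vmn, Gm and Rik symbols kept 18672 of the 21887 genes. Motifs at summits, the share of summits in repeats, lists matched on CpG content, 5′ ends of all transcripts and exon or UTR classes were not analysed here, because they need sequence, strand or transcripts. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.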

Results

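Trim33 occupancy was mapped in Th17 cells, the CD4 T cells that make IL-17 and arise with TGF-beta and IL-6. The data were 1 list of 27050 peaks called on the merged replicates of 2 Trim33 ChIP libraries, with 2 input libraries in the series. The peaks lay on 21 chromosomes, covered 7.15 Mb and had a median width of 227 bp (quartiles 175 and 309 bp). The authors' fold enrichment at the summit ran from 1.91 to 54.6 with a median of 6.00 (quartiles 4.87 and 7.76), and 2993 peaks (11.1%) reached 10-fold or more. The merged list carries no replicate values, so no statement below has an error between cultures.

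The first question was where in the Th17 cytokine loci Trim33 was found. Il17a and Il17f encode the signature cytokines of these cells and are neighbours on chromosome 1 (mm10). The window from 20715905 to 20800274 around both genes held 13 summits. The highest peak in the Il17f locus had a 16.0-fold enrichment, lay inside the gene at 20781038 to 20781469, and ranked 402 of all 27050 peaks. The highest in the Il17a locus had 12.4-fold enrichment and lay at 20736607 to 20736879, 2246 bp above the upper end of the gene. Each of these genes had 5 summits in its locus, and 1 summit of each lay within 1000 bp of a gene end, with 6.18-fold enrichment at Il17a and 9.59-fold at Il17f.

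Il10, which encodes an anti-inflammatory cytokine, had 3 summits in its locus on chromosome 1. The highest had 8.40-fold enrichment and lay at 131025924 to 131026255, 1069 bp above the upper end of the gene. The others had 7.02-fold enrichment at 9141 bp below the lower end and 5.18-fold enrichment inside the gene. No summit lay within 1000 bp of either end of Il10.

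**Figure D1:**
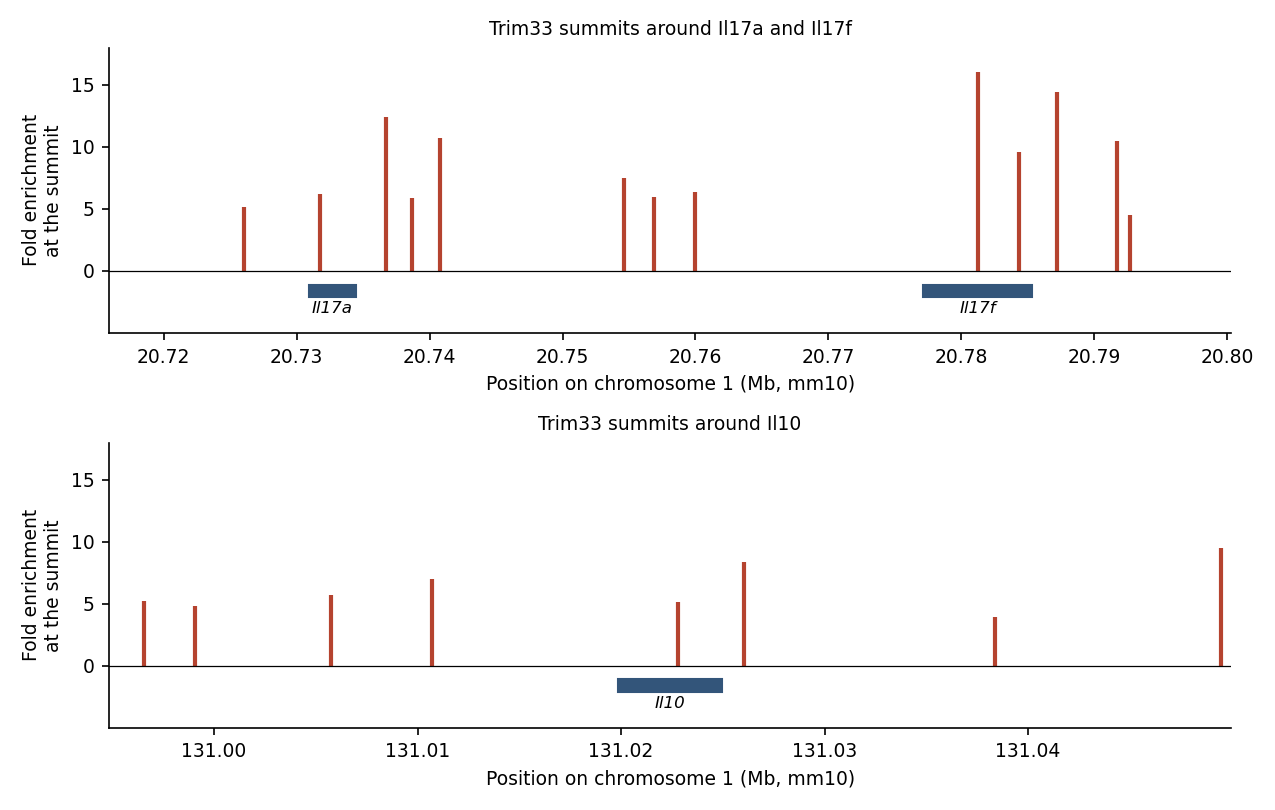
Trim33 summits around Il17a and Il17f and around Il10 by position on chromosome 1 (Mb, mm10), with fold enrichment at the summit as the height of each line and genes as blue boxes. The 13 summits of the Il17a and Il17f window reach 16.0-fold inside Il17f. The 8 summits of the Il10 window reach 9.46-fold at 131049322 to 131049607, outside the 10 kb locus, and include 8.40-fold just above the gene.

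Among other Th17 regulators, the nuclear receptor gene Rora had 18 summits in a long locus, the highest at 9.89-fold. Il23r, the receptor for IL-23, had a peak of 8.85-fold at 97 bp from its upper end. Ccr6, a chemokine receptor of Th17 cells, had 4 summits, the highest at 8.86-fold and 1287 bp below its lower end. Maf, an activator of Il10, had 6.88-fold enrichment at 196 bp from its upper end. Stat3, which transmits IL-6 and IL-23 signals, had 13.1-fold enrichment at 160 bp from its upper end, and Il2 had a peak of 14.2-fold at 2514 bp above its upper end. Il22 and Csf2, both cytokine genes of the Th17 list, had no summit in their loci.

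The TGF-beta pathway genes were occupied as well. Smad4, the shared partner of receptor-activated SMADs, had 3 summits, the highest at 13.3-fold inside the gene. Smad3 had 16 summits up to 11.9-fold, whereas Smad2 had 2 summits up to 4.33-fold. The inhibitory Smad7 had 5 summits up to 8.59-fold. The receptor gene Tgfbr2 had 11 summits up to 9.07-fold, Tgfbr1 had 2 up to 6.20-fold, and the ligand gene Tgfb1 had 7 up to 7.14-fold. Acvr1b, an activin receptor, reached 20.1-fold, the SMAD co-repressor gene Skil 16.3-fold and Pmepa1 15.8-fold. Trim33 itself had 2 summits, of 5.30-fold and 5.21-fold, both inside the gene and within 1000 bp of its lower end. Id1 and Tgfb2 had no summit in their loci.

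The next comparison asked whether summits lay at genes more often than random placement gives. Of the 27050 regions, 7497 (27.7%) had a summit within 1000 bp of an end of a protein-coding gene, against a mean of 3.13% in random placements, an 8.85-fold excess. The excess was 39.8-fold within 100 bp of an end, where 3679 regions (13.6%) lay. Gene bodies away from the ends held 10420 regions (38.5%), which did not differ from placement (0.995-fold, permutation p = 0.515). The classes share 1 total, so a high share at gene ends lowers what is left for the others. With the ends included, gene bodies held 14571 regions (53.9%) against 40.5% in placements (1.33-fold, permutation p = 0.002). Positions farther than 10 kb from a gene held 6396 regions (23.6%) against 49.7% in placements. Positions outside genes but within 10 kb held 2737 regions (10.1%) against 8.47% (1.19-fold). For gene ends, for the regions within 10 kb and for those farther away p was 0.002, the smallest that 1000 placements can give. When each region was moved by only 20 to 100 kb, which keeps the regional density of genes, the excess at gene ends was 5.05-fold. Gene bodies away from the ends then held 0.749 times the share of the moved regions, and positions farther than 10 kb 0.767 times (23.6% against 30.8%). The direction within 10 kb of a gene turned, to 0.826-fold. Gene ends held 27.7% against 5.49% of the moved regions, which lowers all 3 of these shares. They are therefore not read as depletion. With the ends included, gene bodies were at 0.987-fold over the moved regions.

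**Figure D2:**
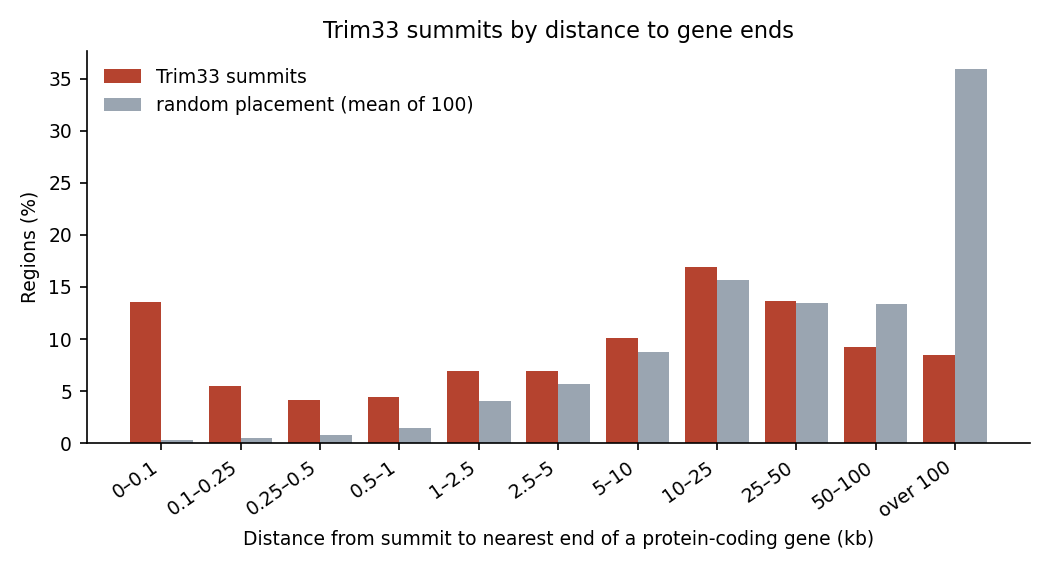
Share of regions (%) by distance from the summit to the nearest end of a protein-coding gene (kb) for the Trim33 peaks and for the mean of 100 random placements. Within 0.1 kb of an end lie 13.6% of the Trim33 summits.

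Gene-end peaks were numerous but not the highest. Their median fold was 5.79 (quartiles 4.69 and 7.51) against 6.07 (4.95 and 7.88) for the other regions. The difference of medians, gene ends minus others, was −0.278 (permutation p = 1e-05, the smallest that 100000 resamples can give). Of the 10 highest peaks, 1 lay at a gene end. The highest, with 54.6-fold enrichment, lay on chromosome 9 at 51982122 to 51982880, 18980 bp from Fdx1. It was followed by peaks near Taar4 (52.2-fold), inside Nell2 (45.8-fold), near Gm45871 (43.4-fold) and near Nampt (41.8-fold). The peak near Bpifc (40.3-fold) was 164 bp from its gene. The others were a peak inside Kdm1a nearest to an end of Luzp1 (38.9-fold), 1 inside Efr3b (38.6-fold), 1 at 125109 bp from 4933412E24Rik (38.5-fold) and 1 at 49035 bp from Chd7 (37.4-fold).

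Gene lists were then compared for summits at gene ends, where 7306 of 21887 protein-coding genes (33.4%) had one. Of the 17 lists, 4 had more members with a gene-end summit than random lists and 1 had fewer. The TGF-beta and SMAD list had 26 of 34 members (76.5%, 2.30-fold over random lists, adjusted permutation p = 0.0034). The list of IL-10 and inhibitory receptors had 13 of 18 (2.17-fold), the NF-kB and AP-1 list 16 of 24 (1.99-fold) and the JAK-STAT list 13 of 19 (2.05-fold). The non-haematopoietic tissue genes, such as Alb and Apoa1, had 1 of 24 (0.125-fold). Adjusted p was 0.0109 for each of these 4 lists. With peaks limited to those at or above the median fold, 1 list passed, the TGF-beta and SMAD list with 17 of 34. The folds of the lists that no longer passed were 1.92 (IL-10 and inhibitory receptors), 2.17 (NF-kB and AP-1) and 2.43 (JAK-STAT), and the non-haematopoietic list had 0 of 24.

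The other 12 lists did not pass at gene ends. The Th17 list had 13 of 24 members (1.63-fold, adjusted permutation p = 0.105), and it passed with a window of 2500 bp (1.74-fold, adjusted p = 0.02). With that window the T cell receptor, Tfh, TRIM and housekeeping lists passed as well (1.74, 1.94, 1.87 and 1.82-fold). The T cell receptor list had 15 of 27, the housekeeping list 12 of 20, the T follicular helper (Tfh) list 8 of 12 and the list of TRIM proteins and silencing partners 10 of 18. Cell cycle genes had 13 of 26, regulatory T cell genes 7 of 15, Th1 genes 8 of 18 and Th2 genes 5 of 15. Markers of other blood cells had 2 of 17 (B cell), 5 of 20 (myeloid and dendritic) and 2 of 13 (CD8 and NK cell).

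Over whole loci, 11796 genes (53.9%) held a summit, and 9 lists differed from random genes of like length. The Th17 list had 22 of 24 members with a summit (1.60-fold, adjusted permutation p = 0.00283). All 27 T cell receptor and identity genes (1.64-fold) and all 18 genes of the IL-10 and inhibitory receptor list (1.73-fold) had one, each with adjusted permutation p = 0.00113. The TGF-beta list had 32 of 34 (1.48-fold), the NF-kB and AP-1 list 22 of 24 (1.74-fold), the regulatory T cell list 14 of 15 (1.58-fold), the JAK-STAT list 17 of 19 (1.44-fold) and the housekeeping list 19 of 20 (1.84-fold). The non-haematopoietic list had 5 of 24 (0.414-fold, adjusted permutation p = 0.0112). Th1 (13 of 18), Th2 (12 of 15), Tfh (10 of 12), TRIM (15 of 18), cell cycle (20 of 26), B cell (12 of 17), myeloid (11 of 20) and CD8 and NK cell genes (6 of 13) did not pass. Calls were lost for the JAK-STAT list without Olfr, Vmn, Gm and Rik symbols among the random genes (1.38-fold, adjusted permutation p = 0.0608). They were also lost for the regulatory T cell list with 50 kb on each side (1.30-fold, 0.0588) and for the housekeeping list in the top set by fold (1.43-fold, 0.402). The non-haematopoietic list lost its call in gene bodies alone (0.334-fold, 0.114), with 50 kb (0.764-fold, 0.134) and with distal summits (0.512-fold, 0.339). Calls were gained for the Th2 list with 50 kb (1.35-fold, adjusted permutation p = 0.0404) and with matching on length and crowding (1.64-fold, 0.032), and for cell cycle genes with 50 kb (1.30-fold, 0.0136).

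When gene-end summits were left out, 11 lists passed, all with more members than random lists. Distal summits were found in 20 of 24 Th17 genes (2.53-fold over length-matched genes), 25 of 27 T cell receptor genes (2.45-fold) and 14 of 15 regulatory T cell genes (2.74-fold), each with adjusted permutation p = 0.00085. The NF-kB and AP-1 list had the largest fold (17 of 24, 2.83-fold), with the same adjusted p. The IL-10 and inhibitory receptor list (15 of 18, 2.60-fold), the JAK-STAT list (15 of 19, 1.99-fold), the TGF-beta list (24 of 34, 1.57-fold) and the Tfh list (9 of 12, 2.03-fold) passed too. So did the Th1 list (11 of 18, 2.02-fold, adjusted p = 0.0128), the Th2 list (10 of 15, 2.51-fold, adjusted p = 0.00382) and cell cycle genes (14 of 26, 1.73-fold, adjusted permutation p = 0.0337). Without Olfr, Vmn, Gm and Rik symbols among the random genes 10 lists passed, and cell cycle genes did not (1.65-fold, adjusted permutation p = 0.0532). The housekeeping list had 6 of 20 (1.23-fold, adjusted permutation p = 0.812). Tests against the housekeeping list and between lists were chosen after the data were seen and were not matched on locus length or gene crowding. Ends of neighbouring genes leave less of a crowded locus in which a summit can count as distal. Matching on length and crowding was run for all summits of a locus, not for distal ones. There it moved the expected share for the Th17 list from 57.4% to 52.5%. For the housekeeping list this was 51.5% and 51.8%, and for the B cell list 53.5% and 58.0%. Random lists of like length had distal summits in 32.9% of members for the Th17 list. For the housekeeping, B cell, myeloid, CD8 and NK cell and non-haematopoietic lists this was lower, 24.4% to 30.4%. Set against the housekeeping list, the Th17 list had more members with a distal summit (Fisher's exact test, adjusted p = 0.00306), but neither at gene ends (13 of 24 against 12 of 20, adjusted p = 0.943) nor over whole loci (adjusted p = 1) was a difference found. At gene ends the TGF-beta, IL-10, NF-kB and JAK-STAT lists did not differ from it past the threshold either (Fisher's exact test, adjusted p from 0.614 to 0.943). Another test set the Th17 list against the Th1, Th2 and cell cycle lists in the same way and found no difference past the threshold (Fisher's exact test, adjusted p = 0.317, 0.472 and 0.0943). Of the 16 lists set against it for distal summits, the Th17 list had more members than the housekeeping list, the B cell list (adjusted p = 0.0113), the myeloid list (0.00306), the CD8 and NK cell list (0.0309) and the non-haematopoietic list (2.28e-05) by the same exact test, and the other 11 did not differ past the threshold.

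**Figure D3:**
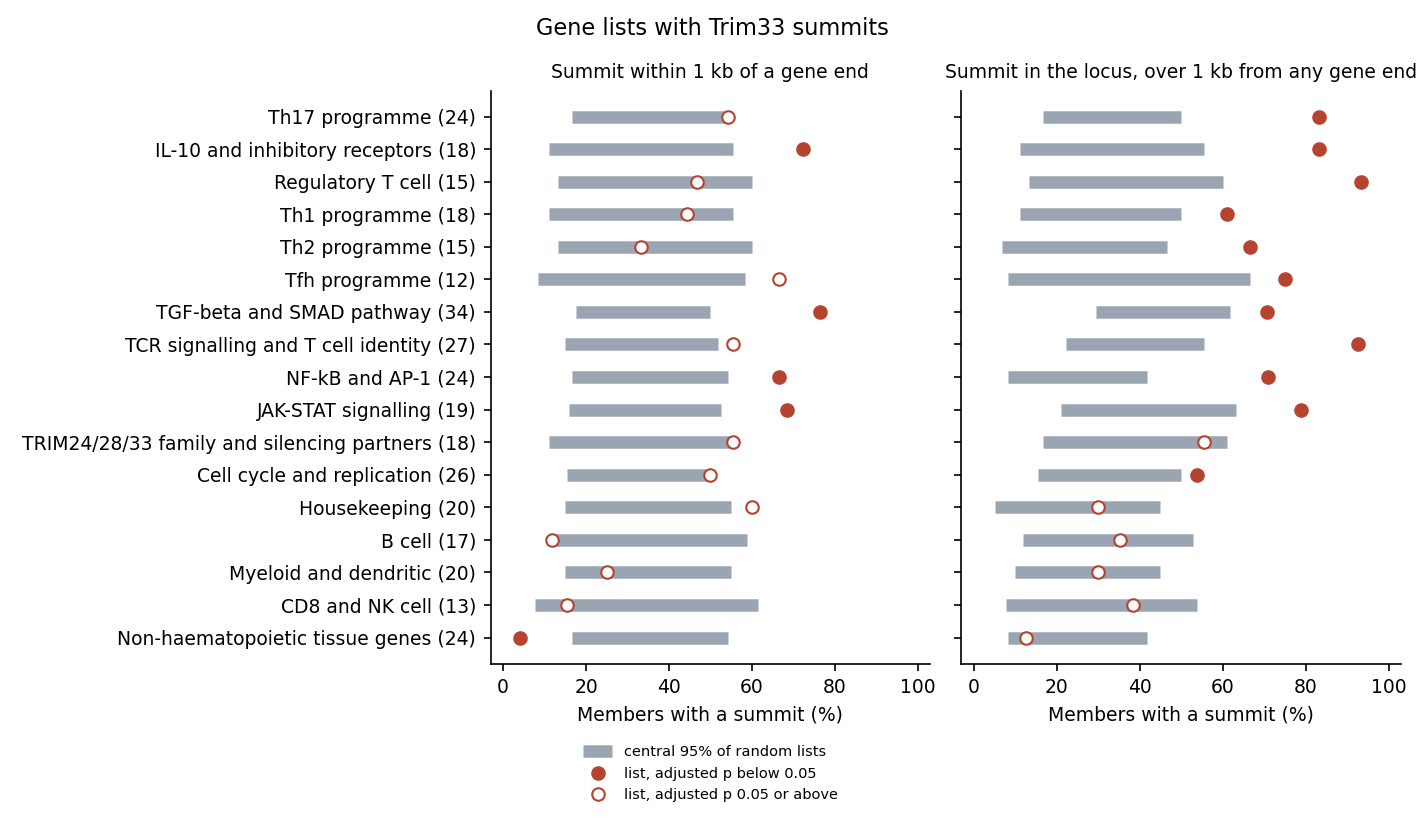
Share of members (%) of the 17 gene lists with a Trim33 summit within 1 kb of a gene end (left) and with a summit in the locus over 1 kb from any gene end (right), with the number of members in brackets. Grey bars are the central 95% of 10000 random lists and filled points have an adjusted p below 0.05, as for the Th17 list with 20 of 24 members on the right.

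The other lists also had members with high peaks and members with none. Tnfrsf4, which encodes the costimulatory receptor OX40, had a 22.3-fold peak at 5082 bp from the gene. Among cytokine and receptor genes of the Th2 list, Il9 reached 18.03-fold, Il4ra 17.9-fold and Ccr8 14.7-fold, while Il5 and Il13 had no summit in their loci. Ifng and Eomes, both of the Th1 list, had no summit in their loci either. The inhibitory receptor genes Havcr2 and Pdcd1 reached 15.2-fold and 14.8-fold, and Bhlhe40 14.9-fold. Bach2, a repressor that restrains effector differentiation, had 38 summits up to 17.8-fold. Jak2 had a 20.6-fold peak at 159 bp from its lower end. Foxp3, the defining factor of regulatory T cells, had no summit in its locus, but it lies on chromosome X, where 29.8% of genes had a locus summit against 56.9% to 68.2% on the autosomes (Olfr, Vmn, Gm and Rik symbols left out). No summit was found either in the loci of the lineage markers Cd8a, Cd79b, Ms4a1, Csf1r and Cebpa. Other markers of these blood cells did hold peaks in their loci. In the myeloid and dendritic list, Zbtb46 had 8 summits up to 16.2-fold and Itgam 1 of 12.4-fold. In the B cell list, Ebf1 had 10 summits up to 12.7-fold and Cd79a 4 up to 9.61-fold. The locus of Fcer2a held 2 up to 10.1-fold, the highest 3860 bp outside the gene. Both lay within 1000 bp of ends of other protein-coding genes and not of Fcer2a, so they may belong to its neighbours. Cd8b1 had 2 summits up to 8.92-fold.

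Chromosomes differed in the density of peaks. Autosomes held 8.28 to 15.3 peaks per Mb, with a median of 10.5, and chromosome X held 2.44. Leaving out genes with Olfr, Vmn, Gm and Rik symbols, 18.2% of the genes on X had a gene-end summit, against 34.96% to 43.6% on the autosomes. The median fold on X was 5.65, against 5.72 to 6.30 on the autosomes. Chromosome Y had 3 peaks.

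**Figure D4:**
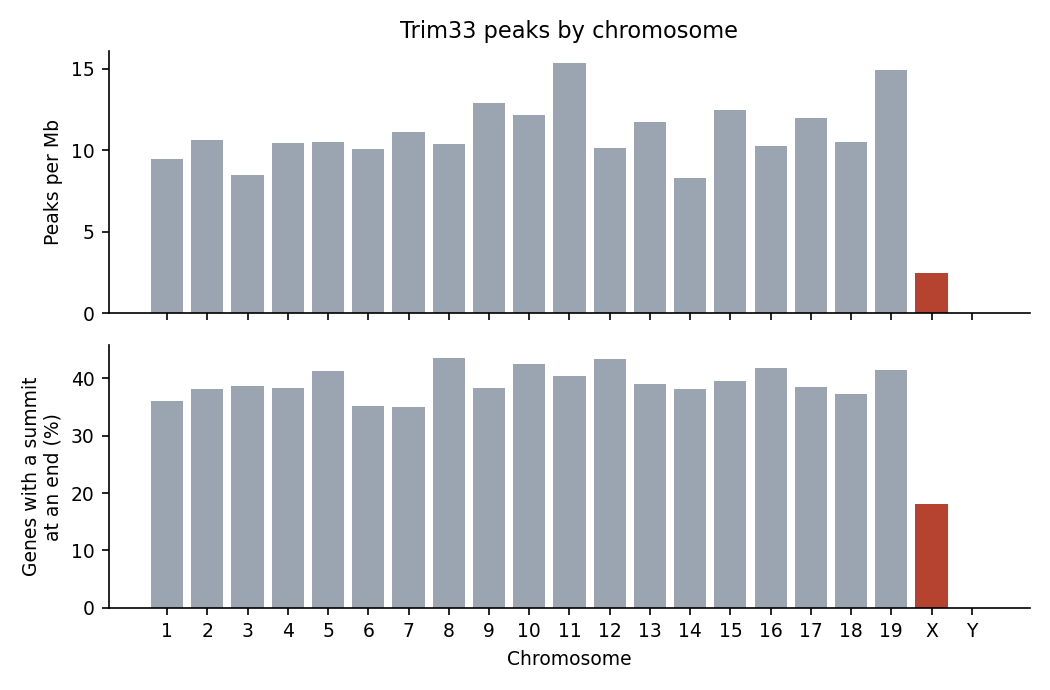
Peaks per Mb (top) and share of genes with a summit at an end (%, bottom) by chromosome, leaving out Olfr, Vmn, Gm and Rik symbols in the lower panel. Chromosome X, in red, has 2.44 peaks per Mb and 18.2% of genes with a summit.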

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

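The excess at gene ends kept its direction and passed its test under all 9 alternatives run, from 4.82-fold (window of 2500 bp) to 14.2-fold (500 bp). The difference in fold was −0.309 with 2500 bp. Alternatives that moved regions, ranked by −log10 q, left out the Sfi1 cluster or changed the random genes were chosen after the data were seen. The stricter sets held 13528 peaks by fold and 13666 by −log10 q, by construction. For gene bodies away from the ends the fold was 1.05 with placement anywhere and 0.749 with regions moved by 20 to 100 kb. With moved regions it was 0.826 within 10 kb of genes and 0.767 farther away. These classes share a total with gene ends, so their folds fall as the share at gene ends rises. The number of lists passing at gene ends was 1 in the top set by fold and 10 with 2500 bp, against 5. The Th17 list at gene ends passed with 2500 bp (1.74-fold). Directions turned for lists that passed under neither setting. At gene ends these were Th2 (0.386 in the top set, 0.873 without Olfr, Vmn, Gm and Rik symbols), B cell (1.07 with 2500 bp) and myeloid genes (1.04 with 2500 bp). By locus they were B cell (0.561) and myeloid genes (0.864) in gene bodies alone, and CD8 and NK cell genes with 50 kb (1.003) or distal summits (1.49). With distal summits and without Olfr, Vmn, Gm and Rik symbols they were CD8 and NK cell genes (1.41) and myeloid genes (0.995). The cause was not tested. Of the 51 list values at gene ends under alternatives 38 kept direction and call, and of the 119 by locus 94 did. No paired analysis was possible because the peak list was made from merged replicates. For the same reason no replicate was left out. Alternatives that need sequence, strand or transcripts (repeats, motifs, CpG matching, 5′ ends of all transcripts) were not run. Depth per library is unknown, so a gene without a peak may lie below detection.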

Other observations

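Other gene classes were looked at after the data were seen. Genes with Rpl and Rps symbols, most of them ribosomal protein genes, had a gene-end summit in 60 of 101 (1.78-fold over random genes). This match on the start of the symbol did not leave out kinase genes with Rps symbols. Zinc finger genes with Zfp symbols had one in 169 of 397 (1.27-fold, adjusted permutation p = 0.0012), but over whole loci the Zfp genes showed no excess (237 of 397, 1.001-fold). Olfactory receptor genes had one in 5 of 1110, keratin genes in 4 of 53 and Hox genes in 1 of 39. Chemokine receptor genes held a summit in 15 of 17 loci (1.78-fold, adjusted permutation p = 0.00385), and a gene-end summit in 7 of 17 (1.24-fold, adjusted permutation p = 0.691). Chemokine genes had a gene-end summit in 3 of 37 (0.243-fold, adjusted permutation p = 0.0014) and a summit in 11 of 37 loci (0.688-fold, adjusted permutation p = 0.148). Of 408 tRNA genes, 72 (17.6%) had a summit within 1000 bp, 5.10 times the share with regions moved by 20 to 100 kb. Of the 55 regions at tRNA genes, 22 were also at an end of a protein-coding gene.

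The share of peaks at gene ends was lower among the highest peaks, by limits on fold chosen after the data were seen. Of 2993 peaks with fold of 10 or more, 22.3% were gene-end peaks, against 28.4% of the rest (Fisher's exact test, p = 6.07e-13). Of 152 peaks with fold of 20 or more, 11 (7.24%, exact binomial interval 3.67% to 12.6%) were gene-end peaks, against 27.8% of the rest (Fisher's exact test, p = 4.09e-10). Summits also lay close together, with a median of 6.98 kb to the nearest other summit against 31.8 kb in random placements. With regions moved by 20 to 100 kb, which keeps the regional density, the median was 13.03 kb, so part of the closeness went with that density.

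Th17 genes held summits more often than genes of like length, and the tests of this pattern were chosen after the data were seen, with the limits on each written before its own result. The tables argue against crowding of neighbouring genes as the whole cause, since lists matched on length and crowding left a 1.75-fold excess (interval 1.39 to 1.89). Without Olfr, Vmn, Gm and Rik symbols among the random genes 1.51-fold was left. This argues against these symbols in the background as the whole cause, although the lower bound of 1.203 lies close to the limit of 1.2 that was set. Silent genes in general are not covered, since other families with few summits, such as keratin genes (11 of 53 loci), stayed among the random genes. Nor were Gm and Rik genes shown to be silent. Binding at any expressed gene stays open. For distal summits the Th17 fold was 2.07 times that of the housekeeping list, with an interval of 1.17 to 5.89. That interval is of a ratio of folds, not an exact binomial interval of a share, and its method is not given here. The folds of distal summits were not matched on gene crowding, and expression was not analysed here.

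Chromosome X held few peaks, and a lower number of genes does not account for it. Peaks per protein-coding gene were 0.431 on X, below the lowest autosome at 0.797. A single copy of X in the cells could lower detection, and the labels give no sex. On chromosome Y, 0% of 20 genes (Olfr, Vmn, Gm and Rik symbols left out) had a summit at an end or in the locus. The 3 peaks on Y lay between 90740998 and 90808938. Cells without Y would give such an absence, but binding may also be missing at these few genes. A single copy of X was thus not tested. No biological explanation was tested.

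The locus with the most summits was that of Sfi1 on chromosome 11, with 53 summits of a median fold of 2.88. These summits formed the largest cluster, from 3127397 to 3202554, which also overlapped Gm51877 and Eif4enif1. The cluster and its test were chosen after its low fold values were seen. A candidate explanation is that the cells hold more copies of this sequence than the assembly, which would raise background and signal together. At like fold (within 10 percent), the median region of the cluster had a −log10 q at percentile 99.7 of regions elsewhere, which is consistent with this technical hypothesis. Some regions of the cluster had as few as 2 matched regions elsewhere, and the test rests on values related to those that drew attention to the cluster, and no biological explanation was tested. Without the cluster the excess at gene ends was 8.91-fold.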
